A study of Mus musculus with 16 samples.

How the data were processed

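The data are 16 two-colour Agilent arrays on tail DNA of C57BL/6 mice: 1 father, 1 mother and 6 progeny, each hybridised against the same reference male with the mouse in Cy3 on 1 array and in Cy5 on the other. Groups and dyes were taken from the labels of the 2 channels. Progeny numbers are those of the labels and were not used for pairing, and the sex of progeny is not stated in them.

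Per the file headers, the scanner images were read with Agilent Feature Extraction 10.7.1.1 under its standard comparative hybridisation protocol, on probe positions of assembly mm9. The processed signals in the deposited files are intensities that this software had background-subtracted, detrended and scaled between dyes by a linear factor, per the file headers. Raw median intensities of spot and local background were deposited beside them, and a column of log10 ratios of red over green. The authors' value table holds log2 ratios of the same arrays. Its columns correlated at 0.991 to 0.998 in size with the scanner's red over green ratio, with the sign turned on arrays with the mouse in Cy5, so it gives reference over mouse. Its column medians ran from −0.0055 to 0.014, and how it was centred is not given in the sources used here. It served as an alternative only.

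Each array held 973116 spots, 966371 of them probes and 6745 controls. Control spots and spots marked as non-uniform or population outliers were left out. There were 114 to 246 such outlier spots per array, and 1672 on the array with progeny 1 in Cy3. No spot was saturated. At least 99.3% of probes were well above background in either channel of every array. Spots of 1 probe were averaged, log2 of the mouse's over the reference's processed signal was taken, and each array was centred on its median over autosomal probes, with no loess or quantile step. The 2 arrays of a mouse were then averaged. The number of arrays limits the precision, and SE values over probes measure the spread between probes of 1 mouse.

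Intervals were called in each mouse alone. The noise SD came from the differences of neighbouring probes. Windows of 3 to 1000 consecutive autosomal probes with a score, |sum| over the noise SD times the square root of the probe number, of at least 6 were taken from the highest score down. They were kept where the mean reached 0.3 in size and each dye orientation alone had the same sign and at least 0.5 of the mean. The same caller on the half-difference of the 2 arrays of a mouse, where copy number cancels, was the control. A progeny call counted as present in a parent when that parent's mean over the same probes had the same sign and at least 0.5 of the size. Calls of all mice that overlapped were merged. The regions named are the 12 with the highest score, plus the 10 highest-scoring progeny regions in neither parent, by a rule written before the data were examined. For a test, regions of known level were set into the difference of the 2 arrays of each mouse. The dye effect of the other mice was removed first, and the 2 orientations were simulated with random noise. The caller found 100% of 3-probe losses at −1 and of 3-probe gains at 0.58. It found 84.4% of 3-probe gains at 0.4, and 100% of 10-probe gains at 0.4. These rates leave out the dye effect present in the real arrays.

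Tests over the family were planned per gene. The files pair no probe with a gene and no annotation of this assembly was used here, so autosomal windows of 25 neighbouring probes took the place of genes, a choice made after seeing the data. Gene list tests, tests of named genes, settings of probes per gene and corrections for GC content were not run. limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment) tested the mean of 8 mice against 0, and the mean of 6 progeny against that of 2 parents. The named windows are the 10 highest and 10 lowest of those past an adjusted p of 0.05 with the same sign in all 8 mice. On simulated data with 200 of 38016 windows changed, the first test found all changes of 0.1, 0.3 and 0.58, with 9 to 11 false calls. The simulated noise was independent between mice and centred on 0. It leaves out the shared reference, the family and the dye effect. Per the file headers, arrays were scanned on 4 days, the parents on 1 and the progeny on 3, and each slide held 1 array, so scan day entered as a random block and slide could not be tested. Single probes were counted where both arrays of a mouse passed a log2 ratio of 1, with opposite signs as the control.

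Alternatives, fixed before the data were examined except where stated, were normexp background correction of the median signals with an offset of 50, centring on all probes, subtraction of a running median over 2001 probes, only the 938329 probes well above background on all arrays, outlier spots kept, the log10 ratio column, the deposited value table, other score, length and size limits, each dye orientation alone, other rules for parents, trend and robust moderation, and each mouse left out in turn. Mean signals were planned for normexp, and the median signals were used in their place. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.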

Results

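DNA copy number was measured by array comparative genomic hybridisation, in which the DNA of a test animal and of a reference animal is labelled with different dyes and competes for the same oligonucleotide probes. The test animals were 1 C57BL/6 father, 1 mother and 6 of their progeny, all from the unexposed family of a study on male mice kept under 1 mGy of gamma rays per day for 400 days. The question addressed by the design is which copy number changes appear in offspring and in neither parent, here as the background level without irradiation. Tail DNA of each mouse was hybridised against tail DNA of 1 reference male of the same colony on 2 arrays with the dyes exchanged, which gave 16 arrays for 8 mice. The 2 arrays of a mouse held the same DNA and counted as 1 replicate. Each array carried 950749 distinct probes, of which 950622 lay on autosomes at a median spacing of 2053 bases, 68 on the X chromosome and 23 on the Y chromosome. Positions are those of mouse assembly mm9 given in the files. No gene names were attached to the probes, so regions are given by position alone. All ratios below are log2 of the test mouse over the reference male.

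The sex chromosomes fixed the direction of the ratios. The median over X probes was 0.97 in the mother and 0.01 in the father, and the median over Y probes was −2.21 in the mother and 0.04 in the father, against a male reference. Among progeny, whose sex the labels do not give, the X median was 0.0047 in progeny 1 and 0.96, 0.97, 0.97, 0.94 and 0.96 in progeny 2 to 6. The Y median was 0.05 in progeny 1 and −2.13, −3.07, −2.16, −2.67 and −2.10 in progeny 2 to 6. A single added X copy therefore read as 0.94 to 0.97 on these arrays, where an exact doubling would read 1. With normexp background correction the negative Y medians shrank to between −0.53 and −0.27. No interval within the X chromosome was called in any of the 8 mice after centring each mouse on its own X median, over only 68 probes.

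**Figure D1:**
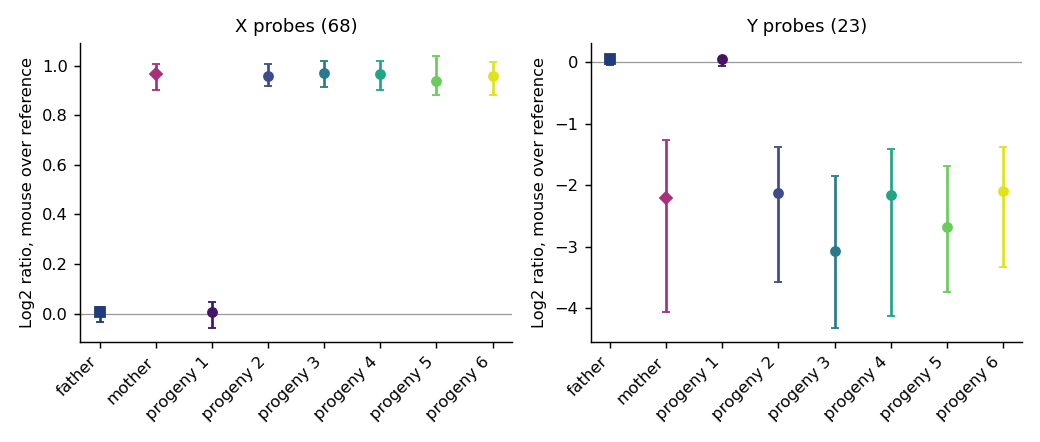
Median log2 ratio of the 68 X probes (left) and 23 Y probes (right) for each mouse over the reference male; points are medians of the mean of 2 dye orientations and bars span the quartiles of the probes. The mother lies at 0.97 on X and −2.21 on Y, and the father at 0.01 and 0.04.

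One long interval was altered in an offspring and in neither parent. On chromosome 8, from base 17385782 to 17491329, 52 consecutive probes spanning 106 kb averaged −0.96 ± 0.02 (SE over probes) in progeny 1, a ratio of 0.514. The array with progeny 1 in Cy5 gave −0.98 and the array with it in Cy3 gave −0.94. The father averaged −0.01 ± 0.01 and the mother −0.03 ± 0.01 over the same probes, and progeny 2 to 6 lay between −0.02 and 0.00. The log2 ratio of 1 copy over 2 is −1. This was the highest-scoring interval of the data set, with a score of 65.8 against a threshold of 6. It was also the only 1 of the 421 progeny calls absent from both parents that held at least 10 probes, a count that was 7 with a calling limit of 0.2 and 4 on either dye orientation alone. Half-differences of the 2 arrays of a mouse, in which copy number cancels, gave 0 calls of 10 or more probes in the 8 mice, and 1 such call once the dye effect seen in the other mice was removed. Each mouse is a single animal, so the comparison has no replicate test beyond the 2 arrays.

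**Figure D2:**
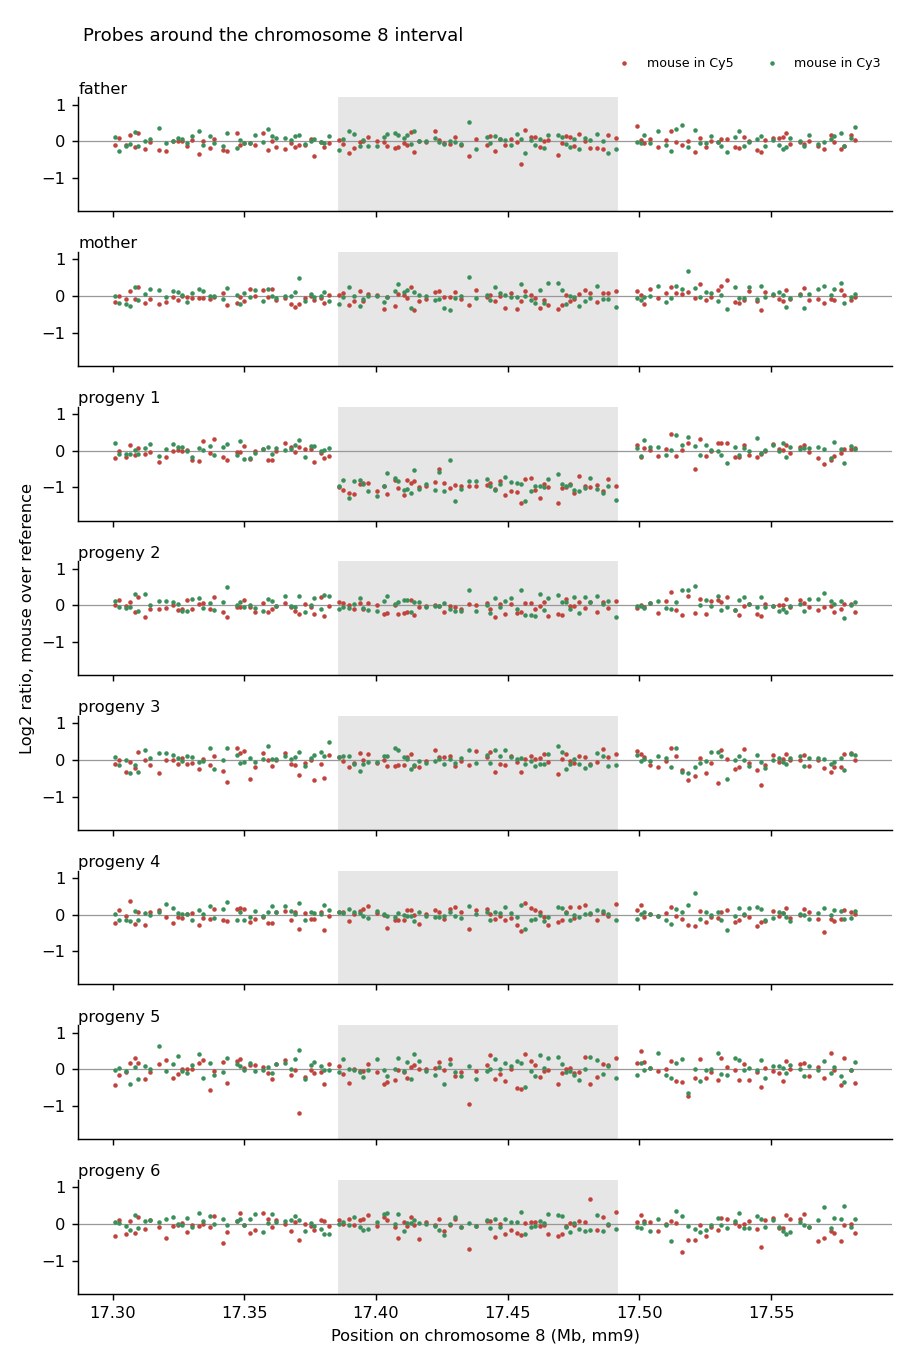
Log2 ratio of single probes over the reference along chromosome 8 (Mb, mm9) in each of the 8 mice; red points are arrays with the mouse in Cy5, green points arrays with the mouse in Cy3, and the shaded span is the called interval. Progeny 1 drops to a mean of −0.96 over 52 probes, while both parents stay at −0.01 and −0.03.

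Other long intervals were carried by 1 parent and by part of the litter. On chromosome 4, from 101110482 to 101270535, 74 probes over 160 kb were higher in the father at 0.56 ± 0.01, in progeny 1 at 0.56 ± 0.01 and in progeny 3 at 0.57 ± 0.01. The mother and progeny 2, 4, 5 and 6 lay between −0.01 and 0.01. A level of 0.58 is the log2 ratio of 3 copies over 2. On chromosome 13, the interval called in progeny 4, from 74596234 to 74756248, held 16 widely spaced probes, some of them near 0, and was lower in the mother at −0.42 ± 0.07 and in progeny 1, 2, 3 and 4 at −0.46 ± 0.08, −0.44 ± 0.08, −0.43 ± 0.09 and −0.42 ± 0.06. Inside it the mother's own call held 9 probes at −0.57, and the longest calls of progeny 1, 2 and 3 held 8 probes at −0.69, −0.64 and −0.67. Over the 16 probes the father averaged 0.02 ± 0.02, progeny 5 −0.05 ± 0.03 and progeny 6 0.01 ± 0.02. The chromosome 4 gain thus occurred in 2 and the chromosome 13 decrease in 4 of 6 progeny, and progeny 1 and 3 had both. Each dye orientation alone gave 0.54 and 0.58 in the father on chromosome 4, and −0.41 and −0.43 in progeny 4 on chromosome 13.

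**Figure D3:**
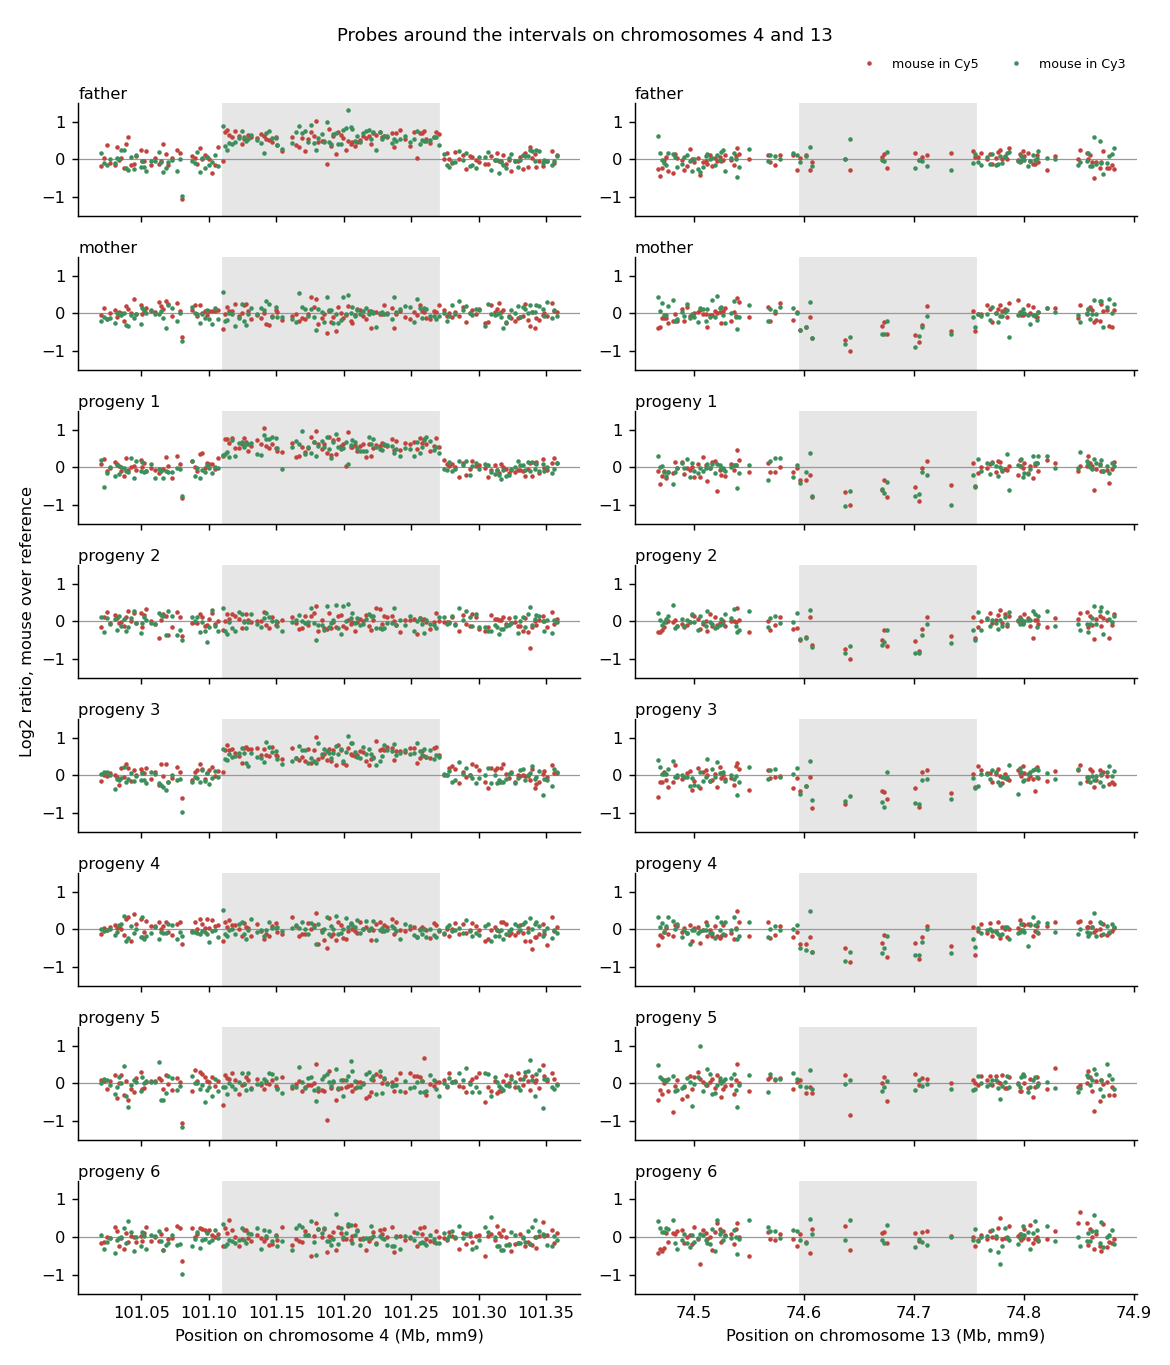
Log2 ratio of single probes over the reference along chromosome 4 (left) and chromosome 13 (right), in Mb of mm9, for each of the 8 mice; colours give the dye of the mouse and shading the called interval. The chromosome 4 span lies at 0.56 to 0.57 in the father, progeny 1 and progeny 3, and the chromosome 13 span at −0.46 to −0.42 in the mother and progeny 1 to 4.

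Several regions differed from the reference male in the whole family. On chromosome 10, from 33897213 to 33933441, 19 probes were called lower in all 8 mice, at −0.59 ± 0.02 (SD, n = 8), with a range of −0.64 to −0.57. The log2 ratio of 2 copies over 3 is −0.58. On chromosome 14, from 53430657 to 54332051, 91 probes over 901 kb averaged −0.27 ± 0.03 (SD, n = 8) and ranged from −0.32 in the mother to −0.23 in progeny 4 and 5. The whole span was called lower in the mother, and overlapping calls of 62 and 55 probes were made in progeny 3 and 4. Progeny 5 had a 3-probe call in the other direction inside it, at 0.44. The mother's value was −0.24 with normexp background correction and −0.27 on its Cy5 array alone, both short of the calling limit of 0.3.

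Windows of 25 neighbouring probes were tested over all mice. Several of the lowest overlapped the regions on chromosomes 10 and 14 above. They average the same ratios as the calls, so this is not separate support. Of 38016 windows, 5324 passed an adjusted p of 0.05 in limma against the reference, 1897 higher and 3427 lower. Most of these shifts were small, with a median size of 0.027, and 16 windows reached 0.1. The lowest window, on chromosome 10 from 33898897 to 33954511, averaged −0.42 ± 0.01 (SE, n = 8, limma adjusted p = 5.94e-29). The next lowest included 5 adjoining windows on chromosome 14 between 53195755 and 54405220, with means of −0.31 to −0.14, and a window on chromosome 3 from 25365855 to 25446265 at −0.18 ± 0.02. The chromosome 3 window was not lower throughout the family, with −0.02 in the father and in progeny 1 and −0.26 to −0.20 in the other mice. The highest windows lay on chromosome 14 from 26775762 to 26944936, at 0.19 ± 0.01 (SE, n = 8, limma adjusted p = 7.88e-20), and from 26730185 to 26773605, at 0.18 ± 0.01. A window on chromosome 11 from 3031505 to 3086513 averaged 0.13 ± 0.01, but 0.02 and not past the threshold on the Cy3 arrays alone. The same sign in 8 of 8 mice was required for a window to be named. The test sets 8 mice against 1 reference animal and leaves out that animal's own spread. The 8 mice are parents and their offspring, yet the SE and p values treat them as independent animals. The excess of lower windows was absent with normexp background correction, at 2887 higher and 2933 lower, and with the median of probes, at 1902 and 1652, and without the weaker arrays of progeny 5 and 6 the count fell to 3085.

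Another set of short runs was low in the mother and in progeny 2 to 6, and near 0 in the father and progeny 1. On chromosome 3, from 25417435 to 25432738, 3 probes averaged −1.64 ± 0.34 (SE over probes) in the mother and −1.72 to −1.57 in progeny 2 to 6, against 0.05 in both the father and progeny 1. Runs of 3 probes on chromosome 9 from 35853071, chromosome 5 from 123592752, chromosome 6 from 104236953 and chromosome 11 from 112955152 followed the same order with means of −0.72, −0.66, −0.58 and −0.61 in the mother. In the mother a single probe carried the decrease in each of these 4 runs, at −2.11, −1.83, −1.64 and −1.83. That probe has no value for progeny 5 in the chromosome 5 run, whose mean there was −0.13, and the median of that run was −0.39 to −0.65 in progeny 2, 3, 4 and 6, where another probe was low too. On chromosome 14, from 61798066 to 61815412, 11 probes averaged −0.24 ± 0.06 in the mother and −0.32 to −0.24 in progeny 2 to 6, against −0.06 ± 0.03 in the father and −0.0042 in progeny 1. This run was singled out after its values were seen, since it holds a call of at least 10 probes outside the naming rule. The opposite direction occurred on chromosome 8 from 102132083 to 102244157. There 39 probes were at 0.31 ± 0.03 in progeny 4, the only mouse past the limit of 0.3, but also at 0.27 ± 0.03 in the mother and 0.21 to 0.27 in progeny 2, 3, 5 and 6. The father and progeny 1 averaged −0.01 ± 0.02 and 0.01 ± 0.02. The value of progeny 4 fell to 0.29 with only probes well above background. The mother and progeny 2 to 6 were the mice with X medians of 0.94 to 0.97 and Y medians of −3.07 to −2.10.

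**Figure D4:**
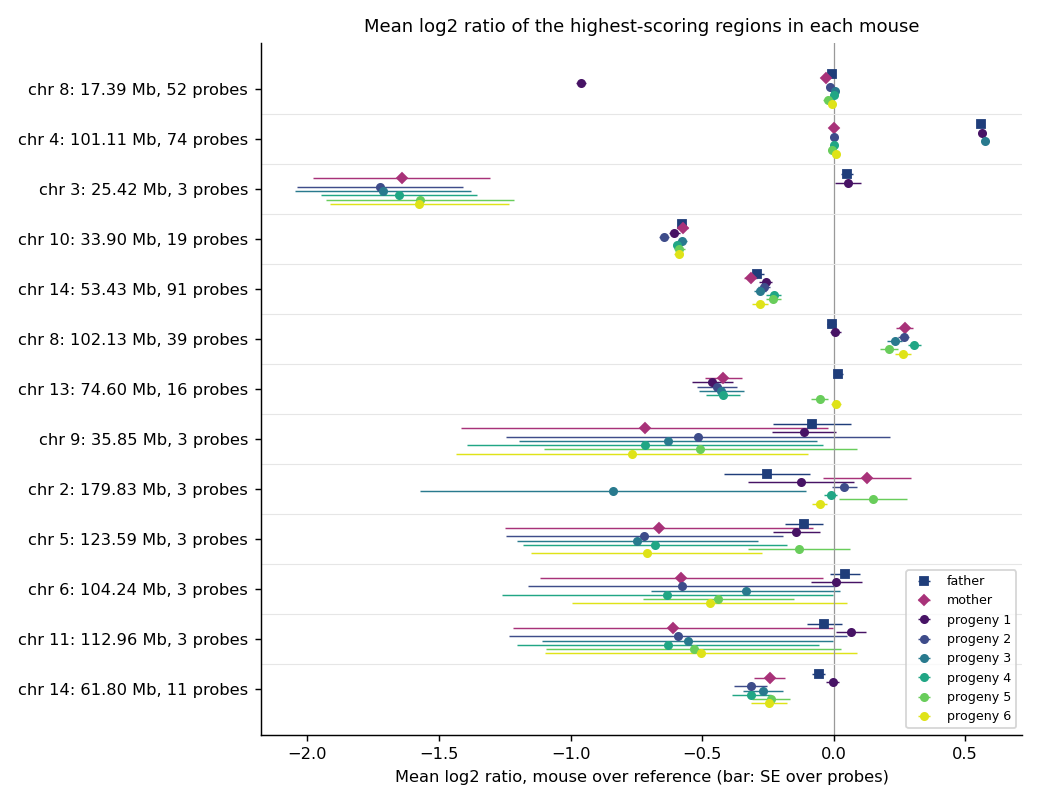
Mean log2 ratio over the reference, for each of the 8 mice, of the 12 highest-scoring merged regions and of the 11-probe run on chromosome 14; bars are SE over probes, and row labels give chromosome, start and number of probes. Progeny 1 stands alone at −0.96 on chromosome 8, all mice lie between −0.64 and −0.57 on chromosome 10, and the 3-probe runs have the widest bars.

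In total 1256 autosomal intervals were called, 245 higher and 1011 lower, which merged into 968 regions. Calls of 3 probes made up 1095 of them, or 87.2%, and only 19 calls in 7 regions held at least 10 probes. The father had 400 calls, the mother 86, and progeny 1 to 6 had 154, 116, 95, 36, 225 and 144. Progeny 2 held 96 of the higher calls, which fell to 149 without it. The father held 386 of the lower calls, which fell to 625 without him. Without the rule that both dye orientations carry a call the total was 1714. The half-differences of the same arrays gave 143, and 738 with the dye effect of the other mice removed. Of the 1714 and the 738, the father held 428 and 59, and the mother 167 and 120. Progeny 1 to 6 held 212, 200, 139, 63, 315 and 190, against 96, 94, 72, 54, 144 and 99 in the second control. The controls were not split by parent, so they give no false call count for progeny calls in neither parent. Each control took its noise SD from its own values. The dye effect widens that SD in the first control, so its short runs needed a larger mean, and 143 can understate false calls. The short calls depended on the processing. The total fell to 489 with normexp background correction, and to 360 when the median of the probes also had to reach 0.3. It was 275 when windows were called anew with at least 5 probes, while 61 of the 1256 calls held that many.

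Of 770 progeny calls, 421 had a comparable ratio in neither parent, 178 in the father only, 85 in the mother only and 86 in both. This split depended on the rule for parents. It was 300, 161, 112 and 197 when 0.33 of the progeny mean was enough. With an overlapping call required in the parent it was 561, 155, 43 and 11. Under the main rule those in the father only numbered 57, 2, 26, 4, 63 and 26 in progeny 1 to 6. The father had the most calls himself. No rate of random matches was estimated, so the split does not measure inheritance. By the main rule the calls in neither parent numbered 55, 70, 44, 16, 144 and 92 in progeny 1 to 6. Apart from the chromosome 8 interval of progeny 1, the 9 highest-scoring of these regions held 3 probes each. They included a decrease of −0.94 in progeny 5 on chromosome 2 from 118754211, a decrease of −0.84 in progeny 3 on chromosome 2 from 179828390, and increases of 0.76 in progeny 5 on chromosome 7 from 57791773 and of 0.74 in progeny 6 on chromosome 1 from 89478036. In 1 of the 9, on chromosome 6 from 59724528, the absence from the parents was marginal, with −0.78 in progeny 5, −0.38 in the father and −0.30 in the mother, and overlapping calls in both parents. With normexp background correction, which damps the ratios of dim probes, all 9 lay within 0.11 of 0, where the chromosome 8 interval read −0.86. In each of the 9 the strongest probe was not well above background on all arrays, so that leaving out such probes kept only 1 or 2 of the 3. All 52 probes of the chromosome 8 interval were kept. The count in neither parent became 38 with normexp background correction and 163 without dim probes, and it was 277 without progeny 5 and 185 without progeny 5 and 6.

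The mean of the progeny did not pass the threshold against that of the parents in any window. This test compares group means, so it is not suited to a change in 1 offspring, such as the chromosome 8 interval of progeny 1. With limma 0 of 38016 windows passed an adjusted p of 0.05 for the mean of 6 progeny minus the mean of 2 parents, and 1318 had an unadjusted p under 0.05. With scan day as a random block limma also gave 0, and 1547 at an unadjusted p under 0.05. The parents were scanned on 1 day and the progeny on 3 others, so scan day and generation cannot be told apart. On simulated windows with noise independent between mice, a difference of 0.1 was found in 73.5% of cases and one of 0.3 in 100%.

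At the level of single probes, 261 autosomal probe values passed a log2 ratio of 1 in the same direction on both arrays of a mouse, and 89 passed it in opposite directions. These counts were 127 and 2 with normexp background correction, and 182 and 8 without dim probes. Progeny 5 held 89 of the former and 47 of the latter, the father 52 and 3. Without progeny 5 the totals were 172 and 42. The 2 arrays of a mouse correlated at a mean of −0.32 over autosomal probes, and arrays of different mice labelled the same way at 0.41, so the dye dominated single-probe values. These are correlations across probes, which are not independent replicates. The noise SD of the mean of 2 arrays ran from 0.078 in progeny 4 to 0.12 in progeny 5. The background-subtracted median Cy3 signal was 99.1 to 135 on the arrays of progeny 5 and 6 and 181 to 308 on the others.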

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

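Among 50 values compared across the 6 progeny, 15 had 1 mouse whose gap to its nearest littermate was too large a part of the whole range by Dixon's 95% limit. Chance gives about 1 in 20, but 41 of the 50 are regions and windows picked by their values, 10 of them for a call in an offspring and in neither parent, so that rate does not apply to them. The other 9 values hold 5 of the 15, among them the X and Y medians of progeny 1, which lie at the level of the father. Of the tests below, the one on every probe low in the mother alone was set before its result was seen, and all others were chosen after.

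Progeny 1 stood apart on chromosome 8 from 17385782 to 17491329, at −0.96 against −0.02 in the nearest littermate. Noise or a fault of 1 array is argued against by the weaker dye orientation, at −0.94; calling required 0.5 of the mean in each orientation, but there were 19 calls of at least 10 probes with and without that rule, so it removed none of this length. A loss carried by a parent is argued against by the lower parent, at −0.0291; the interval was picked for parents under 0.5 of the progeny value, but it also had the highest score of all regions, which does not depend on the parents. Progeny 1 shared 2 long intervals each private to 1 parent, the chromosome 4 gain and the chromosome 13 decrease, but an outside mouse of the same colony could carry these too, so a sample that is not from this litter stays open. With that left open, a loss that arose in the germ line of a parent or early in progeny 1 is a hypothesis only, for which an independent measurement in parents and offspring would be the test.

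Progeny 1 also stood apart in runs that were low in the mother: it read 0.0542 on chromosome 3 from 25417435, 0.0666 on chromosome 11 from 112955152, −0.0042 on chromosome 14 from 61798066 and −0.024 in the 25-probe window on chromosome 3. It was likewise alone in its X median of 0.0047, its Y median of 0.0458 and its value of 0.0059 on chromosome 8 from 102132083. The X and Y medians of the father were 0.0052 and 0.0429, and progeny 2 to 6 lay near the mother on both chromosomes. Progeny 1 thus read as a male among female littermates would, and these 2 medians do not bear on its parentage. The 5 runs of 3 probes had their lowest probes at −2.31 to −1.64 in the mother, beyond 1 copy of 2, and at −0.37 to 0.06 in the father. Offspring with her loss and 1 unaltered copy from him would read about −1. Progeny 2 to 6 read −2.37 to −2.24 on chromosome 3, −2.10 to −1.70 on chromosome 9 and −1.87 to −1.65 on chromosome 11. These values argue against a loss inherited from the mother alone, if the father holds 2 copies. On chromosome 6 progeny 3 and 5 were nearer, at −1.04 and −1.01. Progeny 1 read at least −0.34 at each run, but its parentage is open. Whether probes that also bind Y sequence account for these runs stays open: over all 19 autosomal probes low in the mother alone, against 50 low in the father alone, 62.5% of progeny values were below −0.5 where the Y probes of that mouse were low and above it where they were not, between the bounds set for either reading. At the lowest probes of the runs 29 of 29 values, 100%, did so, but this restates how the runs stood out and tests nothing further, and the probe sequences were not matched to a genome here.

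The father had 400 calls, 386 of them lower, which sets much of the total. Dim probes are not the whole cause, since without them he still had 329 calls, 2.67 times the next mouse. Weak arrays are argued against too: his lower median Cy3 signal was 189, above that of progeny 1, 3, 5 and 6, which had fewer calls. Over his 386 lower calls the mother, who inherited nothing from him, averaged −0.14 and the progeny −0.27 to −0.06. All mice share 1 reference male, so runs picked for a low ratio in the father favour probes high in that reference. Such an excess alone would lower the other mice alike. They ran from −0.273 ± 0.007 (SE over calls) in progeny 5 to −0.062 ± 0.004 in progeny 4. Progeny 4, and progeny 2 at −0.095 ± 0.005, lay above the mother at −0.145 ± 0.005. These values argue against the reference as the whole cause. Its part cannot be told apart from a shift at particular probes shared by several mice. GC content and DNA quality were not tested.

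Progeny 3 read −0.84 on chromosome 2 from 179828390, where the nearest littermate read −0.12. Progeny 5 read −0.94 on chromosome 2 from 118754211 and 0.76 on chromosome 7 from 57791773, and had 89 single probes past 1 in the same direction on both arrays, against 37 in the nearest littermate. Progeny 6 read −0.67 on chromosome 2 from 6180045, against −0.11. The array with progeny 1 in Cy3 had 1672 outlier spots and the array with progeny 2 in Cy5 had 246.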

How the results depend on the processing

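The alternatives with windows of 10 and 50 probes, the median rule, the mean rule before windows, calls of at least 10 probes and the set without progeny 5 and 6 were chosen after seeing the data. None of the 189 alternative values of named regions and 400 of named windows changed sign, but part of this was fixed in advance. Windows were named for the same sign in all 8 mice, so leaving mice out could not turn their mean. Trend and robust moderation leaves that mean as it is. Calls needed the same sign in each dye orientation, so neither orientation alone could turn a named region. Among all these values, 23 of regions and 6 of windows no longer passed their limit. Of the 23, 18 were the 9 short progeny regions under normexp correction and without dim probes, which removes the strongest probe of each. The total of 1256 calls became 168 with a mean of at least 0.5, 360 with the median rule, 489 with normexp, 2138 and 251 with scores of 5 and 8, 275 with at least 5 probes, and 555 and 502 on Cy5 and Cy3 arrays alone; without each mouse it ran from 856 to 1220. The 421 progeny calls in neither parent became 69 with a mean of at least 0.5, 728 without the orientation rule and 147 with the median rule. They became 38 with normexp, 163 without dim probes, 903 and 64 with scores of 5 and 8, and 185 without progeny 5 and 6. Calling anew with at least 5 probes gave 117, while 24 of the 421 held at least 5 probes and 1 held at least 10. Without each progeny mouse in turn the count ran from 277, without progeny 5, to 405, without progeny 4. Leaving out a parent removed only its own calls and kept it in the rule for parents. The count of 421 was therefore fixed in advance there. Calls of at least 10 probes in neither parent stayed at 1 except for 7 with a mean of at least 0.2 and 4 on either orientation alone. The 5324 windows against the reference became 17267 on Cy5 and 18754 on Cy3 arrays alone, where the dye effect does not cancel, and 3085 without progeny 5 and 6, and ran from 3734 to 5030 without each mouse; normexp turned the split of 1897 higher and 3427 lower into 2887 and 2933, and the median of probes into 1902 and 1652. Progeny against parents gave 1 window on Cy3 arrays alone and 0 in the other settings, including without each mouse (0 to 0), where a lone parent is assumed to vary like the other mice. With normexp the Y median was −0.41 in the mother and −0.47, −0.45, −0.53, −0.27 and −0.32 in progeny 2 to 6. The X medians of progeny 5 and 6 were then 0.76 and 0.75, as that step adds to dim signals. Without normexp, the Y median of progeny 1 was −0.0762 on its Cy5 and 0.19 on its Cy3 array. The 261 single probes became 803 and 37 at limits of 0.8 and 1.5, 127 with normexp and 137 without progeny 5 and 6, and ran from 172 to 250 without each mouse, the lowest without progeny 5. The mean correlation of the 2 arrays of a mouse was −0.45 with normexp. The cause of these changes was not tested except where stated. Gene list tests, GC corrections and settings of probes per gene were not run. No paired analysis was possible because the parents are single mice with no number shared with progeny. Signal over background was lowest on the arrays of progeny 5 and 6, whose noise SD of 0.12 and 0.109 was the highest, so that a run of few probes needs a larger mean there to reach the same score.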

Other observations

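The 19 autosomal probes at or below −1 in the mother and above −0.5 in the father, a set chosen on the parents alone, did not behave alike in the litter. Of these, 5 were not well above background on all arrays, and the probes given below were. At 5 of them no offspring was below −0.5, and at 7 of them 5 offspring were. By the same limits 50 probes were low in the father alone. Values were uneven among offspring at several probes, in no single order. The probe on chromosome 3 at 132549431 read −1.38 in the mother, −1.22, −1.25 and −1.04 in progeny 2, 4 and 6, −0.43 and −0.30 in progeny 3 and 5, and 0.17 in progeny 1. Probes on chromosome 4 at 114585758 and chromosome 16 at 40851536 were likewise nearer to 0 in progeny 3 and 5 than in progeny 2, 4 and 6, with −0.65 and −0.50 in progeny 3 and −0.35 and −0.24 in progeny 5. The probe on chromosome 5 at 109220847 went the other way, with −1.37 and −1.31 in progeny 3 and 5 and −1.02, −1.08 and −1.10 in progeny 2, 4 and 6. Each value is 1 probe on 2 arrays, and the unevenness was noticed after seeing the values and not tested.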
